A study of Mus musculus with 16 samples.

How the data were processed

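The data came from the striatum of 8 mice that carried an inducible Cre recombinase under the astrocyte gene Aldh1l1 together with RiboTag, an allele that places a haemagglutinin tag on a ribosomal protein in cells with Cre activity. Per the labels, 4 mice received a control adeno-associated virus (Y481, Y482, Y483 and Y485) and 4 received a virus for human PMCA2 (Y486, Y487, Y489 and Y490), a calcium pump of the plasma membrane that lowers calcium signals in the cell. Each mouse gave 1 input library, made from the cleared tissue lysate, and 1 immunoprecipitated (IP) library, made from RNA bound to the tagged astrocyte ribosomes. The 16 libraries formed 4 groups of 4, and the unit of replication was the mouse. The virus is called PMCA from here on.

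Per the labels, libraries were stranded, ribosomal RNA was depleted, and sequencing ran on an Illumina HiSeq. The submitters' processing notes name the mm10 genome build, STAR, HTSeq, edgeR and limma, without versions or settings. The strand setting and the treatment of reads that match several places are not given in the sources used here. The deposited values were log2 CPM (reads scaled to the effective size of the library) for 13277 genes, per library, with no pooling of replicates. Genes with few reads had been left out by the authors, and each listed gene had at least 5 reads over all libraries. The lowest deposited log2 value was -0.66 in every library.

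Whole reads were recovered from the deposited log2 values. After the lowest value was subtracted on the linear scale, 100% of the values were whole multiples of 1 read within 0.01 reads, and the largest deviation was 7.75e-10 reads. The deposited values matched a mean prior count of 0.25 reads, scaled to library size. Effective library sizes rebuilt with the trimmed mean of M values (TMM) differed from the deposited ones by at most 1.73e-14 in relative terms. Over the listed genes the libraries held 198462 to 686343 reads. Reads are not independent molecules, since no molecular identifiers were used, so floors and intervals cover counting error only.

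The quasi-likelihood count test planned for these comparisons was not run, although whole reads had been recovered, and the deposited log2 unit was kept. The main test was instead limma 3.58.1 in R 4.3.3 on the deposited log2 CPM values, with a variance trend and robust moderation (statmod 1.5.0). A gene was tested when its CPM reached the equivalent of 10 reads at the median library size in at least 4 of the libraries fitted and it had at least 15 reads in them. p-values were adjusted with the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. All adjusted p-values of single genes come from limma. Fold changes are differences of mean log2 CPM with the deposited prior count. For genes with few reads they can understate or overstate the change. Labels were read from the sample table with jsonlite 2.0.0.

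The treatment was compared within the 8 IP libraries and within the 8 input libraries. IP was compared with input within each treatment, and the difference of the treatment effect between fractions was tested directly, in 1 model over all 16 libraries. The main models had no block for the mouse. The pairing of input and IP comes from the labels, which put both libraries on the same mouse, and a model with the mouse as a replicate block was fitted beside each comparison of paired libraries. Deviations of the paired libraries from their group means correlated, over 2550 genes, with r = 0.14, 0.06, 0.10 and 0.17 in the control mice Y481, Y482, Y483 and Y485, and 0.06, 0.17, 0.18 and -0.01 in the PMCA mice Y486, Y487, Y489 and Y490. For Y490 the input library of another PMCA mouse correlated better (r = 0.09), so its pairing rests on the labels alone.

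Gene lists were tested with camera at a preset correlation between genes of 0.01, with camera at a correlation estimated per list, and with fry, which tests whether the genes of a list move one way on balance. List p-values were adjusted over the lists within a comparison. Exact permutation tests of 4 against 4 mice were two-sided, over 70 labelings, and the smallest p they can give is 0.0286. The lists were plasma membrane calcium pumps, calcium signalling, astrocyte G protein-coupled receptors, GABA and glutamate transport and metabolism, GABA-A receptor subunits, endosomal recycling, immediate early genes, cholesterol synthesis, unfolded protein and integrated stress, heat shock, synapse-regulating secreted astrocyte genes, nuclear-encoded and mitochondrially encoded oxidative phosphorylation genes, cytosolic ribosomal proteins, nuclear-retained noncoding RNAs, interferon response, reactive astrocyte genes, and lymphocyte and antigen presentation genes. Marker lists covered astrocytes, striatal projection neurons, neurons in general, striatal interneurons, oligodendrocytes, their precursors, microglia, endothelial cells, mural cells and fibroblasts, and ependymal cells. Some genes stand in more than 1 list, such as Gfap (astrocyte and reactive astrocyte), Psmb8 (reactive astrocyte and interferon) and Snhg11 (neuronal and nuclear-retained). The mitochondrially encoded list had no member among the listed genes and was not tested. The lists held 644 members, of which 568 were listed, 4 of them under an older symbol.

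The groups, comparisons, lists, alternatives other than those given below as added, and the rule for named genes were fixed before the data were examined. For a treatment comparison the rule took Atp2b2, the mouse gene of PMCA2, and the 8 largest changes in each direction among called genes with at least 20 reads per library in the higher group. Where fewer than 3 genes passed in a direction, the 3 with the smallest p were taken, and from each described list up to 4 called members, or the 2 with the smallest p where none was called. For IP against input it took the 8 largest changes in each direction and up to 3 members of each cell type list, and for the difference of effects the 4 largest in each direction. Slc6a11 and Rab11a were always given for the IP treatment comparison, and predicted or unnamed genes were skipped. Which lists were described gene by gene in each treatment comparison was settled after the list results were seen. The genes 9430020K01Rik, Igfbp5, Prrc2b, Shank3, Peg3 in the IP treatment comparison, and other members of lists given beyond the rule were chosen after their values were seen. Some genes that the rule takes are not reported here.

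Gene names follow the deposited table. Of the 13277 listed genes, 12552 matched the mouse reference annotation GRCm38.p6 by symbol, 661 matched through an older symbol and 64 did not match. Coordinates are those of GRCm38, the assembly of the mm10 build, and 21 names had been turned into dates by a spreadsheet before deposit. The pairwise comparison of replicates within groups covered 24 pairs with a chi-square per degree of freedom of 1.59 to 3.71, so no pair agreed within sampling noise.

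The method was tested on simulated counts with known changes, drawn gene by gene with 1 common dispersion of 0.0122. Only genes with a mean of at least 10 reads were changed. Differences in spread between genes and shared shifts of libraries were left out, so recovery in the real data may differ. For the IP treatment comparison (7107 genes), 23.8% of genes changed 1.5-fold, 84.1% of those changed 2-fold and 100% of those changed 4-fold were recovered, with 1 false call. For input (6010 genes) the shares were 27.4%, 85.0% and 100%, with 6 false calls. For the difference of effects (7554 genes) they were 10.4%, 40.3% and 84.8%, with 3 false calls. For IP against input they were 29.9%, 76.1% and 100% in control mice (7610 genes) and 23.9%, 74.2% and 98.5% in PMCA mice (7572 genes). A simulated shifted list was found in each comparison, and 0 of 20 unshifted lists were called in any of them by camera with the preset correlation. Because genes were simulated independently, that result does not show how the preset correlation behaves for lists of correlated genes.

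Alternatives included median-ratio and upper-quartile factors, no filter and a filter of 50 reads in at least 4 libraries, limma-voom on the recovered reads, an adjusted p under 0.1, the removal of ribosomal and small RNA genes, all 16 libraries in 1 model, only the libraries of a treatment, a covariate for RNA of other cells, the replicate block, and leaving out each mouse. A prior count of 2 reads, the sex of the mouse as a covariate (read from Xist and Y-linked reads), leaving out the 2 shallowest input libraries, the replicate block for list tests, alone and with an estimated correlation, and a permutation of list levels were added after seeing the data. The human PMCA2 sequence, transcript lengths and GC content were not used here.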

Results

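RNA bound to astrocyte ribosomes and RNA of whole striatal lysate were measured in the same 8 mice, 4 with control virus and 4 with PMCA virus. RiboTag precipitation pulls down ribosomes that carry the tagged protein, so IP libraries report RNA engaged by ribosomes of Aldh1l1-expressing cells, and input libraries report the whole tissue. The study asked how lowering calcium signals in striatal astrocytes affects striatal circuits and repetitive behaviour in mice. Over the listed genes, control input libraries held 286799 ± 87922 reads and PMCA input libraries 317415 ± 70488 (mean ± SD, n = 4 each). Control IP libraries held 511217 ± 97109 reads and PMCA IP libraries 494076 ± 147522 (n = 4 each). Read totals did not differ by treatment in input (exact permutation p = 0.629) or IP (exact permutation p = 0.857), and 1 read amounted to about 1.59 to 4.46 CPM. The leading principal component held 85.2% of the variance over 2550 genes and separated IP from input libraries. Xist or Y-linked reads placed 2 mice of each sex in each treatment.

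The precipitate was rich in astrocyte RNA and poor in neuronal and oligodendrocyte RNA in both treatments. All 30 tested astrocyte markers were higher in IP than in input of control mice and all 30 were higher in PMCA mice, with list medians of 3.77 and 3.64 on the log2 scale. All 21 tested markers of striatal projection neurons and all 18 pan-neuronal markers were lower in IP in both treatments. The astrocyte glutamate transporter Slc1a2 rose from 11.60 ± 0.12 to 15.94 ± 0.07 log2 CPM in control mice (SD, n = 4 each; log2 fold change 4.33, SE 0.10, adjusted p = 6.13e-20). The synaptic vesicle fusion gene Snap25 fell from 10.38 ± 0.17 to 5.68 ± 0.80 log2 CPM in the same mice (log2 fold change -4.70, SE 0.29, adjusted p = 3.53e-11).

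Of 8091 genes tested in control mice, limma called 4319 at an adjusted p under 0.05, 2211 higher and 2108 lower in IP, of which 1840 and 1741 differed at least 2-fold. Genes higher in control IP included Gjb6, the gap junction protein connexin 30 (log2 fold change 5.07), the receptor gene Gpr37l1 (4.41), Lfng, a modifier of Notch receptors (5.93), Oplah, an enzyme of glutathione turnover (5.92), the lysine-degrading enzyme Aass (5.86) and AI464131 (5.73). Several genes had almost no input reads, so their ratios are given with 95% counting intervals over the summed reads of a group. The growth factor Mdk had 187 IP and 2 input reads (60.3-fold, interval 16.5 to 502), the hedgehog transcription factor Gli2 had 92 and 1 (59.4-fold, interval 10.4 to 2369), and the retinoid enzyme Retsat had 109 and 2 (35.2-fold, interval 9.50 to 294.0). Acads, a mitochondrial enzyme of fatty acid oxidation, had 87 IP reads and 0 input reads in control mice, and was at least 18.7-fold higher against a floor of 3 reads over the group.

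Genes lower in control IP included Rmrp, the RNA component of a mitochondrial RNA-processing enzyme (log2 fold change -7.91, SE 0.67, adjusted p = 3.86e-07), the arginine methyltransferase Prmt8 (-5.51), Cd4 (-5.50), Zcchc12 (-5.39), Lpcat4 (-5.35) and Tmem158 (-5.31). Among neuronal genes, the opioid precursor Penk fell by 4.72, the substance P precursor Tac1 fell by 4.56, the neuronal nuclear protein gene Rbfox3 fell by 4.10 and the vesicular GABA transporter Slc32a1 fell by 4.01 on the log2 scale. The projection neuron receptor Gpr6 had 1 IP and 39 input reads (60.5-fold lower, interval 10.2 to 2448), and the interneuron neuropeptide Sst had 3 and 104 (53.7-fold lower, interval 17.9 to 265). Of 4 tested interneuron markers all 4 were lower, among them the nitric oxide synthase Nos1 (-4.72) and the choline transporter Slc5a7 with 3 and 51 reads (26.4-fold lower, interval 8.52 to 132). Of 11 oligodendrocyte markers 10 were lower, among them the myelin genes Mog (-5.19) and Cldn11 (-4.28) and the galactolipid enzyme Ugt8a with 2 and 111 reads (86.0-fold lower, interval 23.3 to 719). Of 6 precursor markers 4 were lower, among them Gpr17 (-4.25), Pdgfra (-4.13) and Sox10 with 2 and 49 reads (38.0-fold lower, interval 9.97 to 322).

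Microglial RNA was depleted less than neuronal RNA in the control precipitate, with 8 of 11 markers lower, 1 higher and a list median of -1.40. The complement chain genes C1qc (-3.12) and C1qa (-3.00) and the fractalkine receptor Cx3cr1 (-3.05) were the microglial genes with the largest changes. Of 2 tested endothelial markers the transporter Slco1c1 was higher (3.05) and the growth factor receptor Flt1 lower (-2.94). Of 3 mural and fibroblast markers Pdgfrb was higher (3.12), Pdgfra lower, and Vtn lower with 3 IP and 40 input reads (20.7-fold, interval 6.58 to 104). The only tested ependymal marker, the motile cilia transcription factor Foxj1, had a log2 fold change of 1.502 (SE 0.81, adjusted p = 0.128) and passed without Y487 (0.0133) and with the mouse as replicate block (0.0467).

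In PMCA mice 4019 of 8091 genes were called, 2015 higher and 2004 lower in IP, of which 1621 and 1630 differed at least 2-fold. Genes higher in PMCA IP included the transcription factor Tfcp2l1 with 208 IP and 3 input reads (53.6-fold, interval 18.1 to 262), the nucleotidase Entpd2 (log2 fold change 5.30), the malic enzyme Me1 (5.20), Ccdc80 (5.04), Acsf2 (4.84), the proline-degrading enzyme Prodh (4.84), Steap3 (4.80) and Oaf (4.73). Astrocyte markers with the largest changes there were the zinc transporter Slc39a12 (4.24), Slc1a2 (4.09) and the growth factor receptor Fgfr3 (3.89). Genes lower in PMCA IP included Rmrp (-7.63), the synuclein gene Sncb (-5.67), Syngr3 (-5.37), Cldn11 (-5.36), the histamine receptor Hrh3 (-5.28) and Sprn (-5.06). The asparagine synthetase gene Asns had 3 IP and 134 input reads (57.8-fold lower, interval 19.4 to 284) and C1qtnf4 had 2 and 88 (56.9-fold lower, interval 15.3 to 477). Neuronal genes that were lower included the opioid precursor Pdyn (-4.89), Gpr52 (-4.70), Snap25 (-4.17), the GABA-synthesising enzyme Gad1 (-4.08), Eno2 (-4.01) and Sst (-4.13), with Ido1 at 2 and 52 reads (33.6-fold lower, interval 8.85 to 285) and the neuropeptide Npy at 3 and 46 (19.8-fold lower, interval 6.38 to 99.7). Glial genes that were lower included Mal (-4.55), Sox10 (-3.48), Lhfpl3 (-2.78), Cx3cr1 (-2.69) and the purine receptor P2ry12 (-2.02). Foxj1 was higher (3.52, adjusted p = 0.00117), Pdgfrb was higher (2.85), Vtn was lower (-3.62), and Flt1 had a log2 fold change of -1.98 (adjusted p = 0.0559) and passed without Y485 (0.0241) or Y487 (0.0274).

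In list tests of IP against input, camera with the preset correlation called 21 lists in control mice and 17 in PMCA mice, and 12 and 10 with an estimated correlation. The astrocyte list rose in both (adjusted p = 6.78e-26 and 7.69e-28, and adjusted p = 1.56e-04 and 1.08e-04 with an estimated correlation). The projection neuron list (adjusted p = 9.60e-04 and 6.64e-04 with an estimated correlation), the pan-neuronal list (0.00154 and 0.00104) and the oligodendrocyte list (0.00104 and 6.64e-04) fell in control and PMCA mice. The interneuron list fell in both with the preset correlation (adjusted p = 0.0143 and 0.0334, and adjusted p = 0.188 and 0.243 with an estimated correlation), and without Y489 it did not pass in PMCA mice (0.0671). The precursor list fell in control mice only under the preset correlation (adjusted p = 0.0178, and adjusted p = 0.0531 with an estimated correlation), with 0.0674 in PMCA mice. The microglia list had adjusted p = 0.0137 in control mice (adjusted p = 0.289 with an estimated correlation) and 0.0671 in PMCA mice (adjusted p = 0.425 with an estimated correlation), where the paired model with the mouse as replicate block gave 0.0240 (adjusted p = 0.0824 with an estimated correlation). Endothelial (0.492 and 0.391), mural (0.573 and 0.690), heat shock (0.358 and 0.389), endosomal recycling (0.204 and 0.414) and lymphocyte and antigen presentation lists (0.359 and 0.324) did not pass in either treatment.

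Lists of astrocyte functions were enriched in the precipitate as well. Some share genes with the astrocyte marker list, such as Slc1a2, Gpr37l1 and Chrdl1, so they are not fully separate from it. Secreted genes that regulate synapses rose in 15 of 19 members in control mice and 16 of 19 in PMCA mice (adjusted p = 0.00104 and 6.64e-04 with an estimated correlation). Cholesterol synthesis genes rose in 16 and 15 of 17 members (0.0172 and 0.0155), G protein-coupled receptors in 12 of 17 in each (0.0184 and 0.0131), and GABA and glutamate genes in 14 of 20 in each, with the other 6 lower (0.0186 and 0.0164). Immediate early genes fell in 8 and 6 of 12 members (0.0173 and 0.0275) and GABA-A receptor subunits in 8 of 11 in each (0.0455 and 0.0404). The calcium signalling list fell with 20 and 19 of 35 members lower and 8 and 9 higher (adjusted p = 0.0405 and 0.0802 with an estimated correlation). The calcium pump list fell with 3 of 4 members lower in each (adjusted p = 0.0349 and 0.0802 with an estimated correlation). Reactive astrocyte genes rose in 17 of 21 members in each (preset adjusted p = 4.97e-05 and 3.20e-05, and adjusted p = 0.140 and 0.149 with an estimated correlation). Interferon response genes rose in 23 and 20 of 28 (preset adjusted p = 2.86e-06 and 8.15e-06, and adjusted p = 0.249 and 0.260 with an estimated correlation). Nuclear-retained RNAs fell in 7 and 5 of 8 (preset adjusted p = 0.00413 and 0.0101, and adjusted p = 0.13 and 0.174 with an estimated correlation), and ribosomal protein genes in 11 and 17 of 26 (preset adjusted p = 0.0173 and 0.00197, and adjusted p = 0.307 and 0.196 with an estimated correlation). Unfolded protein and integrated stress genes passed in control mice (preset adjusted p = 0.0173, and adjusted p = 0.134 with an estimated correlation) and had 0.0636 in PMCA mice. Nuclear-encoded oxidative phosphorylation genes passed in control mice (preset adjusted p = 0.0439, and adjusted p = 0.425 with an estimated correlation), not without Y481 (0.0973) or Y482 (0.0661), and had 0.258 in PMCA mice. With the mouse as replicate block and an estimated correlation, 13 and 10 lists passed, among them the reactive astrocyte (0.00877 and 0.00676), interferon (0.0191 and 0.0190) and, in control mice, microglia (0.0329) lists. The GABA-A (0.0517 and 0.0501) and calcium signalling (0.0613 and 0.109) lists did not pass there, nor did the immediate early (0.0501) and pump (0.0733) lists in PMCA mice.

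The fold changes of the 2 treatments correlated with r = 0.927 across 8091 genes, which are not independent replicates, and 1727 higher and 1701 lower calls were shared, against 550.6 and 522.1 for independent lists. Per mouse, the median astrocyte enrichment was 3.67 ± 0.05 log2 units in control and 3.56 ± 0.11 in PMCA mice (SD, n = 4 each; exact permutation p = 0.143), and without Y487 the difference was -0.16 (exact permutation p = 0.0286, the smallest possible with the remaining mice). Microglia markers were depleted by -1.43 ± 0.14 in control and -1.03 ± 0.17 in PMCA mice (exact permutation p = 0.0286, the smallest possible, adjusted over 27 lists 0.257). Projection neuron markers differed by 0.13 between treatments (exact permutation p = 0.457) and pan-neuronal markers by 0.22 (exact permutation p = 0.429).

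**Figure D1:**
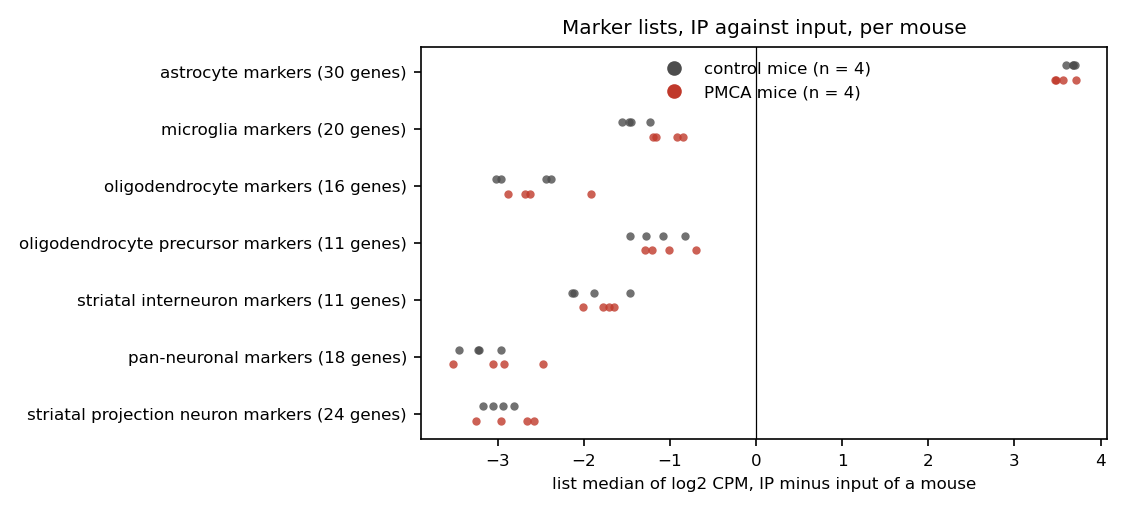
Each point is 1 mouse (grey control, red PMCA, n = 4 each), and the horizontal axis gives the median over a marker list of IP minus input log2 CPM, with 0 for equal levels. Astrocyte markers lie between 3.47 and 3.71 in all 8 mice, neuronal markers lie below 0, and the microglia medians are -1.56 to -1.24 in control and -1.19 to -0.85 in PMCA mice.

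In the astrocyte precipitate, 36 genes differed between PMCA and control mice, 27 higher and 9 lower with PMCA. The pump gene itself, Atp2b2, was 4.23-fold higher in PMCA IP (7.84 ± 0.21 against 9.93 ± 0.50 log2 CPM, SD, n = 4 each). The complement chain genes C1qc and C1qa and the interferon-induced genes Oasl2 and Lgals3bp were higher, beside the extracellular sulfatases Sulf1 and Sulf2. The cell cycle inhibitor Cdkn1a fell from 6.71 ± 0.57 to 4.45 ± 0.72 log2 CPM and the receptor gene Eda2r fell from 5.52 ± 0.54 to 3.33 ± 0.59. Slc6a11, the GABA transporter GAT-3, had a log2 fold change of 0.04 (SE 0.14, adjusted p = 0.941), and Rab11a, a GTPase of recycling endosomes, had -0.53 (SE 0.20, adjusted p = 0.252).

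Atp2b2 lies on chromosome 6 from 113743831 to 114042613 (GRCm38) and had 110.75 reads per control and 492.75 per PMCA IP library (log2 fold change 2.08, SE 0.21, adjusted p = 6.05e-04). The virus carries a human cDNA, so its reads reach the mouse gene only where the sequences are alike. The gene with the smallest p, 9430020K01Rik (current symbol Jcad, a junction-associated protein, chromosome 18 from 4590792 to 4682869), rose from 6.63 ± 0.51 to 8.82 ± 0.27 log2 CPM (log2 fold change 2.19, SE 0.21, adjusted p = 3.02e-06). C1qc (chromosome 4 from 136889801 to 136892936) rose from 2.67 ± 0.80 to 5.72 ± 0.88 log2 CPM, or 3.25 to 24.5 reads per library (log2 fold change 3.05, SE 0.57, adjusted p = 0.00456). C1qa (chromosome 4 from 136895916 to 136898844) rose by 2.95 (SE 0.60, adjusted p = 0.0295). C1qc was not called without Y489 or Y490 (up to 0.13). C1qa was called only without Y481 or Y487 (otherwise up to 0.164). With a covariate for RNA of other cells they had 0.48 (SE 1.41) and 1.49 (SE 1.53). The heparan sulfate endosulfatases Sulf2 (1.61, SE 0.27, adjusted p = 0.00115) and Sulf1 (1.57, SE 0.34, adjusted p = 0.0209) rose together. The postsynaptic scaffold gene Dlgap2 (1.63, adjusted p = 0.00640), the centrosomal gene Cep250 (1.48, adjusted p = 0.0237) and the interferon-inducible GTPase Tgtp1 (1.69, adjusted p = 0.0237) also rose, and Tgtp1 has a near-identical neighbouring copy that could share its reads. Genes named outside the rule were the imprinted zinc finger gene Peg3 on chromosome 7 from 6703892 to 6730462 (1.45, adjusted p = 0.00115), the growth factor binding protein Igfbp5 (0.91, adjusted p = 1.36e-05), Prrc2b (0.79, adjusted p = 5.35e-04) and the postsynaptic scaffold Shank3 (1.08, adjusted p = 0.0209). Sulf1 was not called without Y482, Y483, Y486 or Y489 (up to 0.103), and Cep250 without Y482, Y489 or Y490 (up to 0.152). Tgtp1 was not called without Y481, Y483, Y485, Y486 or Y489 (up to 0.135), and Shank3 without Y481, Y483, Y489 or Y490 (up to 0.0995).

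Among the 9 genes that were lower, Cdkn1a (chromosome 17 from 29090979 to 29100722) had a log2 fold change of -2.26 (SE 0.34, adjusted p = 5.35e-04) and Eda2r (chromosome X from 97333837 to 97377234) had -2.18 (SE 0.48, adjusted p = 0.0209). Rbx1, a component of cullin ubiquitin ligases, fell by 1.45 (adjusted p = 0.0209), and the neuronal tubulin Tubb3 fell by 1.19 (adjusted p = 0.0343). Hey1, a transcription factor downstream of Notch, fell by 0.84 (adjusted p = 0.0341), and the translation elongation factor Eef1a1, which has many processed pseudogenes, fell by 0.71 (adjusted p = 0.00124). The nuclear import receptor Ipo7 fell by 0.68 (adjusted p = 0.0444), Ppp1r3c, which targets a phosphatase to glycogen, fell by 0.60 (adjusted p = 0.0237), and the glutamate dehydrogenase Glud1 fell by 0.44 (adjusted p = 0.0454). Eda2r was not called without Y481, Y482 or Y483 (up to 0.231), and Rbx1 without Y482 or Y483 (up to 0.11). Tubb3 was not called without Y481, Y482, Y485, Y489 or Y490 (up to 0.137), and Hey1 without Y481, Y482, Y483, Y486 or Y489 (up to 0.153). Ppp1r3c was not called without Y481, Y482, Y483, Y489 or Y490 (up to 0.152), and Glud1 without Y482, Y483, Y485, Y489 or Y490 (up to 0.231). Ipo7 was called only without Y485 (otherwise up to 0.19).

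Immune gene lists were higher in PMCA IP under the preset correlation, and none of them held with an estimated one. Of 27 tested interferon response genes all 27 had a positive fold change (median 0.62, and 0.37 without Y485), and the list rose (preset adjusted p = 9.69e-13, and adjusted p = 0.305 with an estimated correlation). Lgals3bp rose by 1.14 (adjusted p = 0.00311) and Oasl2 by 1.37 (adjusted p = 0.0209), so 2 members were called over all genes and 3 adjusted over the list alone, with Bst2 at 1.24 as the other member. Oasl2 was not called without Y482, Y483, Y486 or Y490 (up to 0.133). Of 20 reactive astrocyte genes 15 were positive (median 0.81, preset adjusted p = 1.68e-09, and adjusted p = 0.305 with an estimated correlation), 0 were called over all genes by limma and 4 adjusted over the list alone. The sugar transferase Ggta1 had 1.02 (adjusted p = 0.0799), the lipid receptor S1pr3 2.41 (adjusted p = 0.0975, and 0.0486 without Y481) and the intermediate filament gene Gfap 1.14 (adjusted p = 0.232). Of 9 microglia markers all 9 were positive (median 1.17, preset adjusted p = 3.01e-08, and adjusted p = 0.140 with an estimated correlation), C1qc and C1qa were called, and 6 passed adjusted over the list alone. Of 6 lymphocyte and antigen presentation genes 5 were positive (median 1.78, preset adjusted p = 7.76e-08, and adjusted p = 0.202 with an estimated correlation), 0 were called by limma and 4 passed adjusted over the list alone. The class II genes Cd74 (2.46, adjusted p = 0.208) and H2-Ab1 (1.90, adjusted p = 0.325) had the smallest p there. Fry gave adjusted p = 0.258 for interferon, 0.242 for reactive astrocyte, 0.0742 for microglia and 0.205 for antigen presentation genes. Over libraries, the mean list levels gave exact permutation p = 0.143 for interferon, 0.114 for reactive astrocyte and 0.0571 for microglia and for antigen presentation genes.

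Metabolic lists were lower in PMCA IP. Of 31 nuclear-encoded oxidative phosphorylation genes 28 had a negative fold change (median -0.32), and the list fell (preset adjusted p = 2.91e-07, fry adjusted p = 0.0354, and adjusted p = 0.133 with an estimated correlation). The complex subunits Ndufa4 (-0.92, adjusted p = 0.0865) and Sdhc (-0.72, adjusted p = 0.111) passed adjusted over the list alone and not over all genes. Of 19 cholesterol synthesis genes 17 were negative (median -0.28), and the list fell (preset adjusted p = 3.92e-04, fry adjusted p = 0.0719, and adjusted p = 0.133 with an estimated correlation), with the sterol sensor Insig1 (-0.68, adjusted p = 0.0799, and 0.0483 without Y489) passing adjusted over the list alone. Of 19 ribosomal protein genes 17 were negative (median -0.25, preset adjusted p = 0.0145, fry adjusted p = 0.229, and adjusted p = 0.305 with an estimated correlation), with Rps15 at -0.45 (adjusted p = 0.464) and Rplp0 at -0.51 (adjusted p = 0.497). That call was lost without Y482 (0.114, median -0.17) and without Y490 (0.0667). Nuclear-retained RNAs were positive in 6 of 7 (median 0.52, preset adjusted p = 0.0105, fry adjusted p = 0.229, and adjusted p = 0.305 with an estimated correlation), with Kcnq1ot1 at 0.73 (adjusted p = 0.118) and Meg3 at 0.88 (adjusted p = 0.446), and the call was lost without Y482 (0.0611). The median of that list was 0.22 without Y483 and 0.30 without Y490. Mean levels over libraries gave exact permutation p = 0.0286, the smallest possible, for oxidative phosphorylation, cholesterol synthesis and pump genes, each 0.219 after adjustment over the lists. The pump genes include Atp2b2.

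The calcium pump list was positive in 3 of 3 tested members (median 0.29, preset adjusted p = 5.42e-05, fry adjusted p = 0.0297, and adjusted p = 0.133 with an estimated correlation), with 1 call over all genes and 2 adjusted over the list alone. The list includes Atp2b2 itself (2.08), the 1 member called over all genes. Its tests are therefore not separate from the rise of that gene. Calcium signalling genes were positive in 21 of 34 (adjusted p = 0.319), with the calcineurin regulator Rcan2 at 0.40 (adjusted p = 0.284) and the kinase Camk2g at -0.35 (adjusted p = 0.308). GABA and glutamate genes were negative in 13 of 20 (adjusted p = 0.166), with Glud1 called and 2 members, Glud1 and the succinic semialdehyde dehydrogenase Aldh5a1 (-0.56), passing adjusted over the list alone. Endosomal recycling genes split 14 to 14 (adjusted p = 0.319), with Rab11a and the transferrin receptor Tfrc (-0.56, adjusted p = 0.164) having the smallest p. The list tests did not pass for G protein-coupled receptors (4 of 17 positive, adjusted p = 0.164), GABA-A subunits (2 of 6, 0.319), immediate early genes (3 of 6, 0.581), unfolded protein and integrated stress genes (10 of 20, 0.491), heat shock genes (5 of 10, 0.883) and synapse-regulating secreted genes (10 of 19, 0.778). The heat shock and synapse-regulating lists had positive medians and a negative test direction.

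Markers of other cells gave mixed results in the PMCA precipitate beside the microglia list. Astrocyte markers were negative in 19 of 30 (median -0.12, adjusted p = 0.581), Ppp1r3c was called, and adjusted over the list alone 3 were higher, among them Clu (0.33) and Aldh1l1 (0.43), and 1 lower. Projection neuron markers were positive in 10 of 13 (median 0.03, adjusted p = 0.320), with the dopamine receptor Drd1a (Drd1) at 0.78 (adjusted p = 0.368) and Pde1b at 0.34 (adjusted p = 0.486). Pan-neuronal markers were positive in 9 of 15 (adjusted p = 0.877), with Tubb3 lower. Oligodendrocyte markers were positive in 3 of 5 (adjusted p = 0.896), with Cnp at -0.14 (adjusted p = 0.786) and Trf at 0.25 (adjusted p = 0.827). Of 2 ependymal markers Foxj1 rose by 1.17 (SE 0.28, adjusted p = 0.0436, not called without Y481, Y482, Y483, Y486 or Y490, up to 0.196), while the list had adjusted p = 0.105 and passed without Y490 (0.0121). Precursor, endothelial and mural lists had 1 tested member each, and no interneuron marker was tested. Malat1 took 0.464 ± 0.1004% of control and 0.675 ± 0.235% of PMCA IP reads (SD, n = 4 each; exact permutation p = 0.143).

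Of 7094 genes tested, limma called 77 at an adjusted p under 0.1, and 918 had an unadjusted p under 0.05. The groups did not overlap in 6.86% of the genes, against 2.86% for chance. The filter of 50 reads gave 22 calls, 17 of them shared with the 36, of which 19 were tested there. Limma-voom gave 23 calls and the model with all 16 libraries 11, all shared with the 36. A covariate for neuronal, oligodendrocyte and microglia RNA gave 0. That covariate differed between treatments (3.53 ± 0.09 against 4.12 ± 0.18 log2 CPM, exact permutation p = 0.0286), and raised the median SE from 0.284 to 0.725. With it all 36 genes kept their direction, 16 of them closer to 0 by over 1.5 times, among them Cdkn1a (-1.23, SE 0.86). Leaving out 1 mouse gave 14 calls without Y483, 17 without Y482, 20 without Y489 and 20 without Y490. Of the 21 named genes called, including 9430020K01Rik, 7 held in all 8 such models, namely Atp2b2, 9430020K01Rik, Cdkn1a, Dlgap2, Eef1a1, Lgals3bp and Sulf2. Peg3, Igfbp5 and Prrc2b, named beyond these, also held in all 8. Of the 21, the other 14 lost the call in 2 to 7 models, with a highest adjusted p per gene from 0.103 to 0.231.

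**Figure D2:**
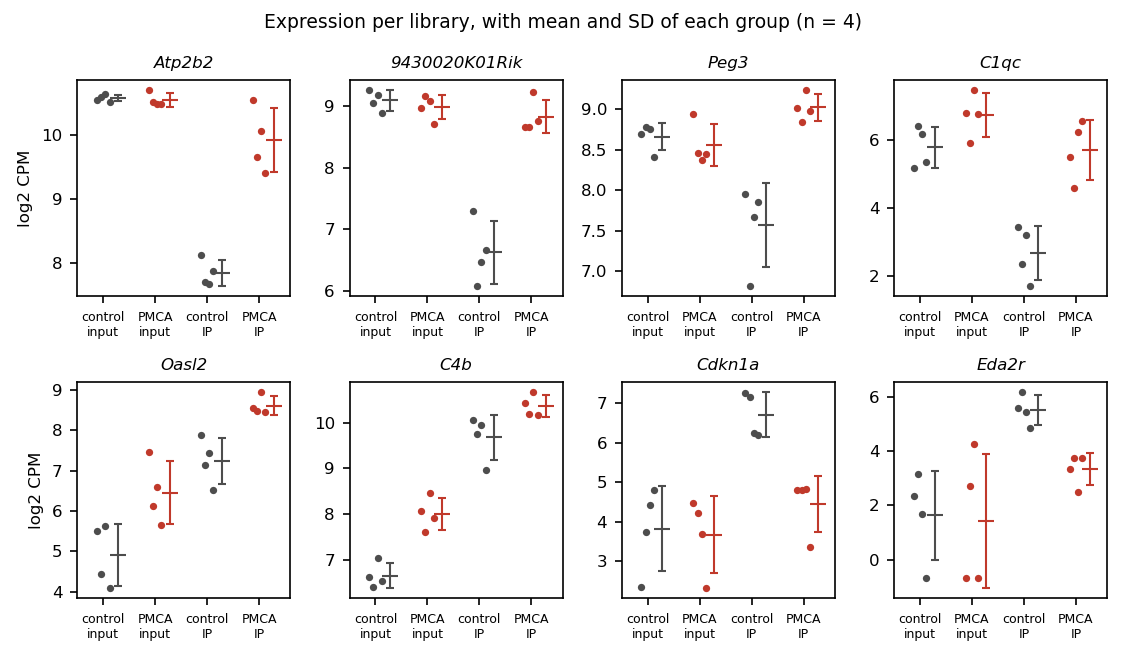
Each point is 1 library, with the mean and SD of each group beside it (grey control, red PMCA, n = 4 each), and the vertical axes give log2 CPM per gene. Atp2b2 lies at 10.58 and 10.55 in control and PMCA input and at 7.84 and 9.93 in control and PMCA IP, and Cdkn1a falls from 6.71 to 4.45 in IP.

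In whole striatal lysate, 2 genes passed the threshold between PMCA and control mice, and another split of the same 8 libraries called 6. H2-T23, a nonclassical class I histocompatibility gene, rose from 4.72 ± 0.56 to 6.78 ± 0.79 log2 CPM, and the complement gene C4b rose from 6.65 ± 0.28 to 8.01 ± 0.35 (SD, n = 4 each). No gene was lower at the threshold in limma. Interferon response, reactive astrocyte, microglia and antigen presentation genes had positive fold changes in nearly all tested members. Atp2b2 stood at 10.58 ± 0.05 log2 CPM in control and 10.55 ± 0.11 in PMCA input (log2 fold change -0.03, SE 0.10, adjusted p = 0.9996).

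H2-T23 (chromosome 17 from 36029977 to 36032701) had a log2 fold change of 2.05 (SE 0.38, adjusted p = 0.0464) and C4b (chromosome 17 from 34728139 to 34743902) 1.36 (SE 0.22, adjusted p = 0.0112). Both belong to families with similar copies that could share reads. The filament gene Vim was next (1.67, SE 0.36, adjusted p = 0.133). On the lower side the smallest p belonged to the cyclin gene Ccnk (-1.62, adjusted p = 0.387), the immediate early gene Nr4a1 (-1.13, adjusted p = 0.585) and the adhesion receptor Bai3 (Adgrb3; -0.57, adjusted p = 0.9996). Of the other pumps, Atp2b4 had 0.56 and Atp2b3 had -0.20, both with adjusted p = 0.9996, and the pump list had adjusted p = 0.992.

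Of 15 interferon response genes all 15 were positive (median 1.29), and the list rose (preset adjusted p = 1.55e-20, and adjusted p = 0.0999 with an estimated correlation). None was called by limma over all genes and 10 passed adjusted over the list alone, with the class I gene H2-K1 at 1.29 and the peptide transporter Tap1 at 1.92 (adjusted p = 0.227 each). Of 10 reactive astrocyte genes 9 were positive (median 1.47, preset adjusted p = 1.68e-14, and adjusted p = 0.0898 with an estimated correlation), H2-T23 was called and 6 passed adjusted over the list alone. Of 11 microglia markers all 11 were positive (median 0.69, preset adjusted p = 1.87e-11, and adjusted p = 0.0999 with an estimated correlation), and 4 passed adjusted over the list alone, with the protease Ctss at 1.46 (adjusted p = 0.227) and C1qa at 1.17 (adjusted p = 0.495). Of 7 lymphocyte and antigen presentation genes all 7 were positive (median 1.72, preset adjusted p = 6.20e-10, and adjusted p = 0.0999 with an estimated correlation), and 5 passed adjusted over the list alone, with H2-Ab1 at 2.002 (adjusted p = 0.617) and H2-Aa at 1.72 (adjusted p = 0.9996). Fry gave adjusted p = 0.125 for interferon and reactive astrocyte genes and 0.271 for microglia and antigen presentation genes. Mean levels over libraries gave exact permutation p = 0.0286, the smallest possible, for interferon and reactive astrocyte genes, 0.274 after adjustment.

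Immediate early genes were negative in 8 of 11 (preset adjusted p = 0.00335, and adjusted p = 0.0999 with an estimated correlation), with 3 lower adjusted over the list alone, among them Nr4a1 and Egr1 (-0.56, adjusted p = 0.9996). That call was lost without Y481 (0.0685) and without the 2 shallowest libraries, Y481 and Y482 (0.232). Astrocyte markers were positive in 17 of 26 (median 0.15, preset adjusted p = 0.0146, and adjusted p = 0.185 with an estimated correlation), with Gfap at 1.27 (adjusted p = 0.133), the 1 member past the threshold adjusted over the list alone, and the water channel Aqp4 at 0.59 (adjusted p = 0.9996). The median was 0.0917 without Y481, and the call was lost without Y482 (0.0587), without Y490 (0.0620) and without the 2 shallowest libraries (0.166). Projection neuron markers were negative in 17 of 21 (median -0.11, preset adjusted p = 0.0387, and adjusted p = 0.129 with an estimated correlation), with the phosphatase inhibitor Ppp1r1b at -0.19 (adjusted p = 0.9996). That call was lost without Y482 (0.188), Y483 (0.119), Y486 (0.0734) or Y490 (0.105) and without the 2 shallowest libraries (0.166). Rn45s, the ribosomal RNA precursor, took 6.23 ± 1.68% of control and 2.75 ± 0.86% of PMCA input reads (SD, n = 4 each; exact permutation p = 0.0286, the smallest possible), and in IP the shares were 3.02 ± 1.33% and 2.93 ± 1.37% (exact permutation p = 0.943).

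Pan-neuronal markers were negative in 11 of 18 (adjusted p = 0.577), with Slc32a1 at -0.41, and passed without Y486 (0.0342). Oligodendrocyte markers were positive in 7 of 11 (adjusted p = 0.590), with Ugt8a at 0.37 and Mobp at 0.30. The list tests did not pass for interneurons (0.507), precursors (0.742), calcium signalling (0.162), G protein-coupled receptors (0.520), GABA and glutamate (0.866), GABA-A subunits (0.507), endosomal recycling (0.787, with a negative median and a positive test direction), cholesterol synthesis (0.866) and heat shock (0.992). They did not pass for synapse-regulating genes (0.742), unfolded protein and integrated stress genes (0.143, passing without Y487 at 0.0276), ribosomal proteins (0.979, passing without Y486 at 0.0307), oxidative phosphorylation (0.227, passing without Y481 at 0.00979 and without Y490 at 0.0382) and nuclear-retained RNAs (0.485, passing without Y481 at 0.00986). The last 2 lists passed also without the 2 shallowest libraries (0.0202 and 0.0392). Endothelial and mural lists had 1 tested member each and the ependymal list none.

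Of 5895 genes tested in input, limma called 2, the same number as at an adjusted p under 0.1, and 212 had an unadjusted p under 0.05. The groups did not overlap in 149 genes (2.53%), against 2.86% for chance. The count was 10 without Y481, 3 without Y487, 0 without Y482, Y485, Y489 or Y490, 11 without the 2 shallowest libraries, 6 with all 16 libraries in the model and 1 with median-ratio factors, with the filter of 50 reads or with limma-voom. C4b was lost without Y482, Y485, Y489 or Y490 (up to 0.225) and H2-T23 without Y482, Y485, Y487, Y489 or Y490 (up to 0.726). Without Y481 the calls included Vim (0.00684), Gfap (0.00764), C1qa (0.00764), H2-Ab1 (0.0104) and H2-K1 (0.00467), and without Y487 Gfap (0.0153) and Ctss (1.11e-04). Of the genes called in IP, 23 higher and 7 lower ones were also tested in input, and none of these was called there by limma. With only 2 input calls, independent lists would share 0.00907 higher genes, so the absence of shared calls carries little information. Across 5072 genes tested in both fractions the treatment effects correlated with r = 0.178, genes not being independent replicates, and 15 of 23 higher and 7 of 7 lower IP calls had the same sign in input. Both fractions come from the same mice, so some of this agreement can arise without a treatment effect.

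**Figure D3:**
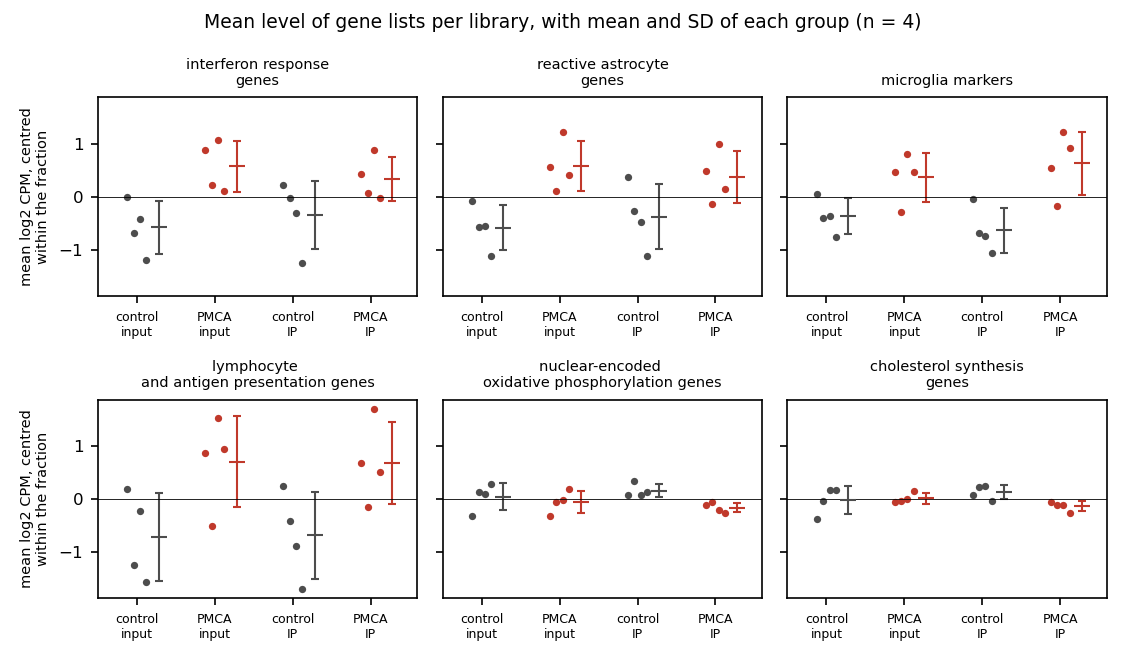
Each point is 1 library, with the mean and SD of each group beside it (grey control, red PMCA, n = 4 each), and the vertical axes give the mean log2 CPM over the tested genes of a list, centred within the fraction. The interferon list stands at -0.57 and 0.57 in control and PMCA input and at -0.33 and 0.33 in control and PMCA IP, with 1 control IP library at -1.23, and the oxidative phosphorylation list stands at 0.16 and -0.16 in control and PMCA IP.

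The treatment effect differed between the fractions for 3 genes, all with a larger rise in IP. Atp2b2 rose more in IP by 2.11 on the log2 scale (SE 0.24, adjusted p = 2.73e-05), with 7.84 ± 0.21 and 9.93 ± 0.50 log2 CPM in control and PMCA IP and 10.58 ± 0.05 and 10.55 ± 0.11 in input (SD, n = 4 each). Control input held more Atp2b2 than control IP, so a rise in astrocytes alone would be diluted in input. The like input levels therefore do not exclude such a rise in the tissue. The effect on 9430020K01Rik differed by 2.30 (SE 0.27, adjusted p = 2.73e-05) and that on Peg3 by 1.56 (SE 0.27, adjusted p = 0.0122). Peg3 stood at 7.57 ± 0.52 and 9.02 ± 0.16 log2 CPM in control and PMCA IP and at 8.66 ± 0.17 and 8.56 ± 0.26 in input.

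Limma tested 8091 genes, 427 had an unadjusted p under 0.05, and no gene had a smaller effect in IP past the threshold. The paired model with the mouse as replicate block called the same 3 genes. Peg3 was lost without Y483, Y487, Y489 or Y490 (adjusted p up to 0.137) and without the 2 shallowest input libraries, which leave 2 genes. In list tests the calcium pump list, which includes Atp2b2, passed (preset adjusted p = 0.00552, and adjusted p = 0.110 with an estimated correlation) and was lost without Y482 (0.123). No other list passed in the unpaired model, with 0.0641 for the astrocyte, projection neuron, immediate early, unfolded protein and oxidative phosphorylation lists, 0.0690 for microglia markers, 0.141 for interferon response genes and 0.450 for reactive astrocyte genes. The paired model with the mouse as replicate block called 11 lists at the preset correlation, among them the microglia list (adjusted p = 0.00980, larger effect in IP). At an estimated correlation it called 0, with 0.160 for microglia and pump genes as the lowest. Camera in the unpaired model also called 0, with 0.110 for pump genes as the lowest. The paired model gave preset adjusted p = 0.0493 for the astrocyte, reactive astrocyte, interferon, unfolded protein and oxidative phosphorylation lists (smaller effect in IP). With an estimated correlation it gave these lists adjusted p = 0.281 to 0.566. The paired model gave the same preset value for the projection neuron, precursor, immediate early and nuclear-retained lists (larger effect in IP). With an estimated correlation it gave these lists adjusted p = 0.281 to 0.392. Without Y485 the unpaired model also called the astrocyte, projection neuron, unfolded protein and oxidative phosphorylation lists (0.0406 each), and without Y486 the ribosomal protein and oxidative phosphorylation lists (0.00717 each). Without Y487 it also called the astrocyte and unfolded protein lists (0.0238 each), the immediate early list (0.0354) and the microglia list (0.0442), and without Y489 the interneuron (0.0305) and projection neuron (0.0105) lists. The lymphocyte and antigen presentation list had a median of -0.07 and a positive test direction (adjusted p = 0.843).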

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

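The tests of carry-over, gene length, p53 targets and single mice in this part, and the permutation tests of list levels, were chosen only after the result was seen. In 150 groups of 4 libraries, over the named genes, 8 held a library far from the other 3, by Dixon's gap test at its 95% limit, against 7.5 expected by chance. Among PMCA IP libraries, Y490 lay apart for Cdkn1a (3.37 log2 CPM, others 4.79 to 4.82), Meg3 (10.33, others 9.09 to 9.30), Ndufa4 (5.17, others 5.86 to 5.98) and Rplp0 (4.72, others 5.74 to 5.93), and Y486 for Drd1a (5.64, others 5.16 to 5.19). Among input libraries, Y487 lay apart for Aqp4 (7.44, others 7.87 to 7.93), Y486 for Atp2b2 (10.71, others 10.49 to 10.52) and control Y483 for Atp2b3 (7.48, others 6.97 to 7.02). Y490 was the shallowest PMCA IP library (347274 reads).

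The treatment effect differed between IP and input, by a direct test of the difference, for 9430020K01Rik (2.30 on the log2 scale), Atp2b2 (2.11) and Peg3 (1.56). Neuronal RNA carried over into the precipitate would raise a gene by no larger a share of its input level than neuronal markers. The rises of the 3 genes were larger than that share, but the genes had been picked for a large rise in IP. The IP rise was at least 0.522 of the input level for the 3 genes (Atp2b2 0.522, 9430020K01Rik 0.703, Peg3 0.852), against at most 0.0683 among 28 neuronal markers. Without 1 mouse the highest neuronal ratio reached 0.107 (Snhg11, without Y486). Carry-over from other cells is not covered by this comparison. Microglia markers had ratios from 0.0162 to 0.611, a range that includes the Atp2b2 ratio. The longest and shortest genes by genomic span differed by 0.116 (log2) in median IP effect, against a lowest confidence bound of 1.03 for the 3 genes. Medians over many genes could hardly reach the effects of genes picked as extremes. This comparison therefore cannot exclude gene length, and transcript lengths were not used. Reads of the viral human PMCA2 that match mouse Atp2b2 could produce the Atp2b2 rise, which was not tested because that sequence was not used here, and more Atp2b2 from the mouse gene remains as open.

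The interferon and reactive astrocyte lists were higher in PMCA IP and PMCA input at the preset correlation, with adjusted p = 0.305 and 0.305 in IP and 0.0999 and 0.0898 in input with an estimated correlation. RNA carried over from other cells may contribute and could not be told apart from a response of astrocytes. The IP rise was 1.41 times the input level at the median of 46 genes, which exceeds its source, but 0.887 without Y485. In input 15 interferon and 10 reactive astrocyte genes passed the filter, against 27 and 20 in IP. Many of these input levels therefore rest on few reads, which makes the ratio uncertain. No single mouse set the sign of the difference, since the lowest list median without 1 mouse was 0.37 (interferon, without Y485). Single mice did move its size, as the interferon median was 0.84 without Y481. Both lists stayed past the preset-correlation threshold without each mouse, a call that did not hold with an estimated correlation.

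For microglia markers, the level minus that of neuronal markers was -0.59 ± 0.46 in control and 0.59 ± 0.64 in PMCA IP libraries (SD, n = 4 each; exact permutation p = 0.0571), and the fold changes and shares below were compared after that test had missed its threshold. More carried-over RNA of all other cells would raise each type by a like factor, but 33 neuronal and oligodendrocyte markers had a median log2 fold change of 0.0577 (SD over markers 0.37) against 1.17 for microglia markers. The gap stayed above 1 SD over markers without each mouse in turn, and was smallest without Y489 (0.14 against 0.93). The IP rise was 0.336 of the input level at the microglia median and at most 0.0683 among those 33 markers, where the types already differed in control IP (0.391 of input for microglia, 0.171 for oligodendrocyte and 0.101 for projection neuron markers). Without 1 mouse the microglia median fell to 0.241 (without Y489) and the highest ratio among the 33 rose to 0.107 (without Y486). More microglial RNA in the tissue or in the precipitate stays open, since in input the microglia list was higher only at the preset correlation (adjusted p = 0.0999 with an estimated correlation, 0.271 with fry) and 0 of 11 markers were called by limma.

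Cdkn1a and Eda2r, both targets of p53, were lower in PMCA IP. A lower level of p53 targets as a group might include both genes, so a list of targets was written after these 2 genes and Mdm2 had been seen. Of the 20 other tested targets 16 had a negative fold change, and their mean level gave exact permutation p = 0.143, which leaves the question open. With the 3 genes included, 19 of 23 were negative (exact permutation p = 0.0286), a value that the choice of genes favours. In input the other targets gave exact permutation p = 0.686.

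The count of genes called was compared over all 35 splits of the same libraries into 2 groups of 4. In IP only 1 split, the treatment itself, called as many as 36 genes, with 14 at most in any other and 0 in 30 of them. In input 2 splits, the treatment included, called 2 genes or more, with 6 genes at most in another, so chance may account for the 2 input calls. For IP against input only 1 split called as many genes in each treatment, with 1 gene at most in another split of control and 0 of PMCA libraries, and for the difference of effects only 1, with 0 in any other.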

How the results depend on the processing

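The sex covariate, the prior count of 2 reads, the models without the 2 shallowest input libraries, the permutation of list levels, the replicate block for lists, alone and with an estimated correlation, and the per-mouse enrichment without 1 mouse were chosen only after results were seen. DESeq2 was not run, and its median-ratio factors were used within limma. The IP count of 36 became 22 with the 50-read filter, which leaves fewer genes to test, 23 with limma-voom, 77 at an adjusted p under 0.1, 11 with all 16 libraries and 0 with the covariate for RNA of other cells, where Atp2b2 had 1.88 (SE 0.59, from 2.08, SE 0.21), Cdkn1a -1.23 (SE 0.86, from -2.26, SE 0.34), C1qc 0.48 (SE 1.41, from 3.05, SE 0.57) and C1qa 1.49 (SE 1.53, from 2.95, SE 0.60). The covariate contains microglia markers, differs between treatments and raised the median SE from 0.284 to 0.725, and with it signs turned for Cnp (0.34), Trf (-0.17), Insig1 (0.0552), Ndufa4 (0.19), Rplp0 (0.54), Kcnq1ot1 (-0.46), Meg3 (-0.0207) and Slc6a11 (-0.13). Leaving out 1 mouse gave 14 (without Y483) to 52 (without Y487) IP calls and Atp2b2 from 1.87 to 2.25, and turned the sign of Trf (-0.0771 to 0.56), Slc6a11 (-0.0799 to 0.14) and input Atp2b3 (-0.31 to 0.0157). IP counts within 1.5 times the main count or equal to it were 38 with median-ratio factors, 35 with upper-quartile factors, 32 without a filter, 36 without ribosomal and small RNA genes, 38 with a prior count of 2 and 54 with the sex covariate. The share of higher genes among IP calls, 75%, was 100% with all 16 libraries, 65.7% with upper-quartile factors, 64.8% with the sex covariate, 63.6% with the 50-read filter and 59.7% at an adjusted p under 0.1, and without 1 mouse it was 53.8% (without Y486) to 88.2% (without Y482). The input count of 2 became 1 with median-ratio factors, 1 with the 50-read filter, 1 with limma-voom, 6 with all 16 libraries and 11 without the 2 shallowest libraries, and ranged from 0 to 10 without 1 mouse. With the 50-read filter IP against input gave 1962 calls in control and 1951 in PMCA mice, where fewer genes were tested. With the replicate block it gave 4313 calls, 4225 shared with the 4319, and 4003, 3909 shared with the 4019, and among named genes and lists the block changed no other call beyond those given with the comparisons. Among lists, IP calls fell from 9 to 2 with fry, 0 with an estimated correlation and 0 by permutation, and input calls from 7 to 0, 0 and 0. For IP against input an estimated correlation gave 12 lists in control and 10 in PMCA mice, and 13 and 10 with the block as well. For the difference of effects 0 lists passed with fry, 0 with an estimated correlation 11 with the replicate block and 0 with the block and an estimated correlation, and 0 to 5 without 1 mouse. The per-mouse difference in astrocyte enrichment ranged from -0.163 to -0.0811 without 1 mouse. The causes of changes not named here were not tested. Of the named genes, 632 of 760 values under an alternative kept sign and side of the threshold in IP, 417 of 443 in input, 728 of 733 and 703 of 709 for IP against input in control and PMCA mice, and 49 of 54 for the difference. A read amounted to up to 4.46 CPM, and depth was not varied.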

Other observations

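The patterns in this part were noticed only after the results were seen, and they are given as values with no test of a cause. Sulf1 (1.57) and Sulf2 (1.61), which edit the same extracellular sugar chains, rose together in PMCA IP. Igfbp5, which binds insulin-like growth factors, rose from 10.62 ± 0.24 to 11.53 ± 0.17 log2 CPM in PMCA IP (SD, n = 4 each).

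Rn45s took 6.23% of control and 2.75% of PMCA input reads (exact permutation p = 0.0286). Malat1 took 1.54% of control and 1.78% of PMCA input reads (exact permutation p = 0.429). Slc1a2 alone took 5.81% of control and 5.45% of PMCA IP reads, against 0.335% and 0.384% of input reads. The per-mouse IP minus input median of the calcium signalling list differed by 0.23 between treatments (exact permutation p = 0.0286, adjusted over the lists 0.257) and that of the pump list by 1.10 (exact permutation p = 0.0286, adjusted 0.257). The pump list includes Atp2b2.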
